A study of Mus musculus with 8 samples.

How the data were processed

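Bone marrow-derived macrophages of floxed Mettl3 mice with Lyz2-Cre (KO) or without it (WT) received PBS or LPS and nigericin, with 2 libraries per group and 8 in all. Doses were 50 ng/ml LPS overnight and 10 µM nigericin for 3 h per the labels of the samples, while the series text gives 1 h or 3 h. RNA was extracted with Trizol and libraries were made with a commercial kit per the labels' protocols, which do not state whether strand was kept. The deposited table holds 1 count per gene and library. Per the submitters' processing notes, Trimmomatic, Bowtie2 and edgeR were used with the mouse genome mm10, without versions, and the tool that made the counts and its annotation are not given in the sources used here. The whole-number values were used as deposited.

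The table held 55401 genes, of which 55141 had a symbol in the GENCODE M21 annotation. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 17470 tested genes with 99.98% of the counts in every library. Total counts lay between 55032057 and 65487739 per library. The 10 most abundant genes took 11.6 to 17.4% of the counts, and 1.84 to 3.36% came from the mitochondrial genome. Composition factors (TMM) lay between 0.888 and 1.068. The common biological coefficient of variation was 0.2151, and the median absolute log2 difference between the libraries of a group was 0.135 to 0.194. Between the libraries of a group, chi-square per degree of freedom was 42.19 to 88.52, so no library repeats another.

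All 8 libraries were fitted together, with 1 coefficient per group and 4 residual degrees of freedom. The 5 contrasts were stimulation in WT, stimulation in KO, genotype with PBS, genotype after stimulation and the difference of both responses. Tests were edgeR's quasi-likelihood F tests (edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment within each contrast at 0.05. Fold changes are those reported by edgeR's test, and standard errors were computed as the unshrunk log2 fold change over the root of F. Against a group with 0 counts a fold is given as a lower bound, with the empty group set to 3 counts in all. The contrasts, tests, gene lists and the rule for naming genes were chosen before the data were examined. On simulated counts with 100 genes changed by each fold, the tests recovered 28 and 70% of genes changed 2-fold and 4-fold in the WT contrast. They recovered 34 and 78% in the PBS genotype contrast, 43 and 67% after stimulation and 11 and 54% in the difference of responses. Unchanged genes called were 13 in the PBS genotype contrast, 4 in WT, 5 in KO, 5 after stimulation and 3 in the difference.

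The 40 gene lists covered the focus of the study, inflammasomes and pyroptosis, necroptosis and apoptosis, m6A, interferon-stimulated genes, NF-kB feedback and cytokines, Toll-like receptors, neutrophil-attracting chemokines, immediate early genes, stress responses, heat shock, NRF2, p53, hypoxia and glycolysis, the respiratory chain from both genomes, ribosomal proteins, S phase, G2 and M phase, histones, cholesterol synthesis, LXR, lysosome, alternative activation, macrophage core, MHC class I and II, SOCS and cytokine receptors, autophagy, ion channels, RNA sensing, nuclear transcripts as a sign of RNA quality, and 8 other cell types. Each was tested with limma's camera (limma 3.58.1, preset correlation 0.01, then an estimated one), adjusted over the 40 lists within a contrast. Named genes were the focus list in every contrast, and the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries. The rule left out predicted genes and added up to 4 members with the smallest adjusted p for each list that passed camera or had at least 3 called members. A repeat of a gene outside its own contrast, and genes named as chosen after their values were seen, are the exceptions.

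Alternatives were DESeq2's size factors in the same fit, library size with no composition factor, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 2 libraries, only the groups compared, a fold threshold of 2, the replicate number as a block, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Exons were not separated, since the counts cover whole genes. Near-identical genes, such as H2-Q6 and H2-Q7, immunoglobulin genes and mitochondrial genes with nuclear copies, may share counts.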

Results

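RNA was sequenced from bone marrow-derived macrophages (BMDM, macrophages grown from mouse bone marrow) of mice in which both Mettl3 alleles were flanked by loxP sites. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA. Macrophages of mice that also carried Cre recombinase under the Lyz2 promoter, which is active in myeloid cells, are called KO here, and those without Cre are called WT. Cells of each genotype received PBS or were stimulated overnight with 50 ng/ml LPS, a bacterial ligand of TLR4. Stimulated cells then received 10 µM nigericin, a potassium ionophore that activates the NLRP3 inflammasome, for 3 h. There were 2 libraries in each of the 4 groups, 8 in all. The libraries held between 55032057 and 65487739 counts. Nothing states that the 2 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The first principal component, with 62.5% of the variance, separated stimulated from PBS libraries, and the second held 11%.

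Mettl3 itself (ENSMUSG00000022160, chromosome 14, 52294841 to 52305128, minus strand, GRCm38) was lower in every KO library than in every WT library of the same treatment. With PBS its level was 13.6 and 13.3 CPM (counts scaled to a common library size) in WT against 5.63 and 6.33 in KO. After stimulation it was 28.2 and 23.4 in WT against 9.08 and 7.87 in KO. The log2 difference between KO and WT was -1.17 ± 0.14 (SE, n = 2 per group, adjusted p = 0.0143) with PBS and -1.61 ± 0.14 (adjusted p = 0.00283) after stimulation. The PBS call was lost without either WT PBS library or either KO PBS library (adjusted p up to 0.0805), and the stimulated call was kept in all 8 fits that left out 1 library. Counts covered the whole gene, so transcripts that lack only the floxed exons would still be counted.

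Of the 22 m6A writers, erasers and readers, 1 was higher and 2 were lower in stimulated KO (3 and 2 adjusted over the list alone, camera adjusted p = 0.776). Beside Mettl3, the m6A reader Igf2bp2 was lower by -1.18 ± 0.15 (adjusted p = 0.0101), and Ythdf2, a reader that promotes mRNA decay, was higher by 0.47 ± 0.08 (adjusted p = 0.0216). The Igf2bp2 call was lost without either stimulated KO library (adjusted p up to 0.0713), and the Ythdf2 call without either stimulated WT library or either stimulated KO library (up to 0.139). These counts, with no composition factor in the scaling, were 3 and 2, so the balance of the list turned. With PBS, Mettl3 was the 1 member of that list past the threshold, with 3 higher and 2 lower adjusted over the list alone.

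**Figure D1:**
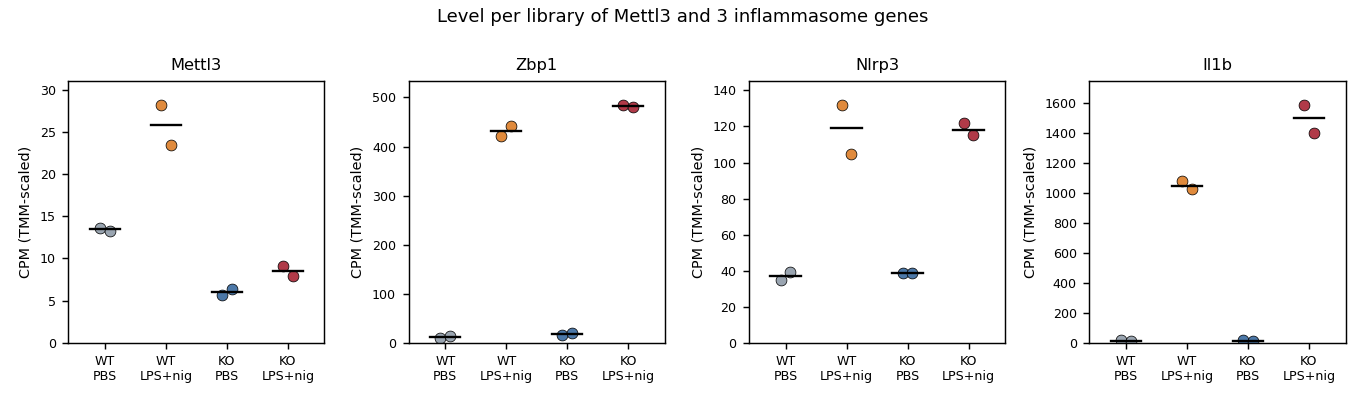
Each panel shows the level of 1 gene (Mettl3, Zbp1, Nlrp3, Il1b) in CPM on an axis that starts at 0, by genotype and treatment. Points are the 2 libraries of a group and the line is their mean, which for Zbp1 was 432 in stimulated WT and 483 in stimulated KO.

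The first comparison asked what LPS and nigericin changed in WT macrophages. Stimulated WT macrophages carried far more mRNA of inflammatory mediators. Il1b, the cytokine matured by the inflammasome, rose by 6.17 ± 0.14 log2 units, Il1a by 7.72 ± 0.26 and Tnf by 7.77 ± 0.19. Lcn2, an iron-binding protein that limits bacterial growth, rose by 10.17 ± 0.28, and Acod1, which makes itaconate, by 9.85 ± 0.27. Nos2, the inducible nitric oxide synthase, had 0 counts in both WT PBS libraries and was at least 6080-fold higher after stimulation, and the interleukin-12 subunit gene Il12b was at least 1660-fold higher. Zbp1, a sensor of Z-form nucleic acids that engages cell death kinases, rose by 5.13 ± 0.19, from 12.3 ± 2.6 to 432 ± 14.1 CPM (SD, n = 2). Genes that fell included the mannose receptor Mrc1 (-4.31 ± 0.11), the scavenger receptor Cd163 (-2.93 ± 0.16), the lipid regulator Pparg (-4.29 ± 0.15) and the lipid-sensing receptor Trem2 (-2.48 ± 0.08). The largest adjusted p among these genes was 2.36e-05, for Il12b. In all, 7082 of 17470 tested genes changed, 3592 up and 3490 down, in edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. Without a composition factor 36.5% of the changed genes were up in place of 50.7%, and the median of all genes moved to -0.197.

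The focus list held 19 genes, of which 15 rose and 0 fell in WT (16 and 0 adjusted over the list alone). For this list the camera adjusted p was 2.21e-08, and 0.16 with an estimated correlation. Nlrp3, the sensor that nigericin engages, rose by 1.68 ± 0.13 and its adaptor Pycard by 1.16 ± 0.13. The protease Casp1 rose by 1.33 ± 0.10, Casp4, a sensor of cytosolic LPS, by 1.69 ± 0.08, and the pore-forming Gsdmd by 1.47 ± 0.07. The necroptosis effector Mlkl rose by 3.03 ± 0.12 and its kinase Ripk3 by 0.79 ± 0.14, while Casp8 was at 0.11 ± 0.10 (adjusted p = 0.441). Il18 rose by 0.59 ± 0.18 (adjusted p = 0.034), a call lost without either WT PBS library, either stimulated WT library or either stimulated KO library (adjusted p up to 0.167). Of the wider inflammasome and pyroptosis list, 16 of 26 rose and 5 fell (19 and 5 adjusted over the list alone, camera adjusted p = 1.65e-05, adjusted p = 0.256 with an estimated correlation), with Mefv, the pyrin sensor, up by 4.39 ± 0.12. Those that fell were 2 to 4 when 1 library was left out. Of 30 necroptosis and apoptosis genes, 13 rose and 4 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.00308, adjusted p = 0.16 with an estimated correlation), with Cflar, an inhibitor of caspase-8, up by 2.74 ± 0.08.

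All 56 tested interferon-stimulated genes rose (56 and 0 adjusted over the list alone, camera adjusted p = 1.10e-29, adjusted p = 0.256 with an estimated correlation). They included the antiviral factor Oasl1 (5.46 ± 0.09), the transcription factor Irf7 (5.24 ± 0.11) and the chemokine Cxcl10 (8.57 ± 0.19). Of 46 NF-kB feedback and cytokine genes 43 rose and 0 fell (45 and 0 adjusted over the list alone, camera adjusted p = 2.99e-24, adjusted p = 0.106 with an estimated correlation). Among them were the acute-phase gene Saa3 (8.52 ± 0.09) and the signalling inhibitor Socs3 (7.01 ± 0.16). All 19 genes of MHC class I presentation rose (19 and 0 adjusted over the list alone, camera adjusted p = 9.46e-14, adjusted p = 0.16 with an estimated correlation). H2-Q6 was up by 7.29 ± 0.08 and H2-Q7 by 6.59 ± 0.09, near-identical genes whose counts may be shared. Of 10 neutrophil-attracting chemokine genes 8 rose (8 and 0 adjusted over the list alone, camera adjusted p = 5.34e-05, adjusted p = 0.193 with an estimated correlation), and of 22 genes of endogenous RNA sensing 14 rose (15 and 0 adjusted over the list alone, camera adjusted p = 8.30e-06, adjusted p = 0.325 with an estimated correlation).

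Of 34 genes of the integrated stress and unfolded protein responses 29 rose and 1 fell (29 and 1 adjusted over the list alone, camera adjusted p = 8.03e-10, adjusted p = 0.16 with an estimated correlation), with the serine synthesis enzyme Phgdh up by 4.88 ± 0.27. Of 20 heat shock genes 14 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 1.59e-04, adjusted p = 0.288 with an estimated correlation). Among 28 hypoxia and glycolysis genes 17 rose and 2 fell (17 and 2 adjusted over the list alone, camera adjusted p = 4.61e-04, adjusted p = 0.16 with an estimated correlation), the glycolytic Pfkl rising by 1.59 ± 0.08. Among 34 nuclear genes of the respiratory chain 25 rose (27 and 0 adjusted over the list alone, camera adjusted p = 2.21e-08, adjusted p = 0.362 with an estimated correlation), with cytochrome c, Cycs, up by 1.90 ± 0.09. Of 32 G2 and M phase genes 2 rose and 20 fell (2 and 21 adjusted over the list alone, camera adjusted p = 1.31e-05, adjusted p = 0.362 with an estimated correlation), with the centromere histone Cenpa at -5.85 ± 0.22. Of 15 fibroblast and stromal markers 1 rose and 12 fell (1 and 12 adjusted over the list alone, camera adjusted p = 2.59e-04, adjusted p = 0.362 with an estimated correlation), with the chemokine Cxcl12 at -1.72 ± 0.15. The counts with library size alone were 27 and 2 for the stress responses, 12 and 3 for heat shock and 17 and 4 for hypoxia.

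The camera test did not pass for the remaining lists in WT, whose risen and fallen members follow. Of 22 NRF2 and oxidative stress genes 10 rose and 4 fell (11 and 4 adjusted over the list alone), with the peroxiredoxin Prdx1 up by 1.68 ± 0.07 and heme oxygenase, Hmox1, by 1.64 ± 0.07. The further counts, each with the same count adjusted over the list alone in brackets, were 5 and 13 of 21 (5 and 13) for LXR and lipid genes, 7 and 13 of 29 (7 and 15) for lysosomal genes and 5 and 13 of 27 (6 and 13) for autophagy. Alternative activation had 5 and 8 of 18 (5 and 9), macrophage core genes 6 and 13 of 27 (8 and 14), cholesterol synthesis 4 and 8 of 22 (7 and 10) and MHC class II 5 and 5 of 14 (7 and 5). Immediate early genes had 14 and 8 of 30 (14 and 8), p53 targets 7 and 3 of 19 (8 and 3), m6A genes 2 and 3 of 22 (2 and 3) and S phase genes 5 and 3 of 32 (5 and 3), which became 5 and 11 without a composition factor. Histones had 0 and 1 of 16 (0 and 1) and mitochondrially encoded mRNAs 0 and 2 of 13 (0 and 1). The balance also turned without that factor for the next 4 lists. Toll-like receptors and adaptors had 6 and 5 of 25 (6 and 5), which became 4 and 7 without the factor. SOCS and cytokine receptor genes had 10 and 3 of 28 (10 and 3), which became 9 and 10, and ion channels 9 and 8 of 28 (11 and 10), which became 6 and 11. Ribosomal proteins had 11 and 0 of 45 (7 and 0), which became 3 and 10. Without the factor the counts were 3 and 13 for LXR, 4 and 18 for lysosome, 3 and 15 for autophagy, 1 and 11 for cholesterol, 1 and 5 for m6A, 0 and 4 for mitochondrial mRNAs, 0 and 2 for histones and 1 and 3 for B and plasma cell genes. Without 1 library the risen genes were 4 to 15 for ribosomal proteins, 1 to 4 for cholesterol, 4 to 7 for lysosome, 3 to 5 for autophagy, 1 to 3 for m6A and 0 to 1 for B and plasma cells. The fallen genes were then 1 to 4 for S phase, 3 to 5 for MHC class II, 3 to 5 for SOCS, 3 to 4 for Toll-like receptors and 1 to 2 for mitochondrial mRNAs. Markers of other cells had 3 and 1 of 8 (3 and 1) for neutrophils, 3 and 1 of 8 (3 and 1) for dendritic cells, 0 and 1 of 4 (0 and 1) for T and NK cells and 2 and 3 of 7 (2 and 3) for B and plasma cells. They had 0 and 1 of 4 (0 and 1) for mast cells and basophils, 0 and 1 of 8 (0 and 0) for erythroid cells and megakaryocytes and 3 and 3 of 10 (3 and 4) for osteoclasts. Nuclear transcripts that mark RNA quality had 0 and 0 of 5 (0 and 0). No camera call in any of the 5 comparisons held with an estimated correlation.

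The second comparison asked the same of KO macrophages. Stimulated KO macrophages showed the same inflammatory mRNAs. Il1b rose by 6.73 ± 0.15, Il1a by 8.25 ± 0.27, Tnf by 7.63 ± 0.18, Zbp1 by 4.76 ± 0.18, Nlrp3 by 1.61 ± 0.13 and Gsdmd by 1.44 ± 0.07. Il6 had 0 counts in KO with PBS and was at least 1010-fold higher after stimulation, and Nos2 was at least 2580-fold higher. Mrc1 (-4.25 ± 0.11), Trem2 (-2.67 ± 0.08) and Pparg (-4.54 ± 0.15) fell, as did Atp6v0d2, a subunit of the vacuolar proton pump (-4.96 ± 0.10). The largest adjusted p among these genes was 8.62e-05, for Nlrp3. In edgeR's test 6839 genes changed, 3527 up and 3312 down. Without a composition factor the median of all genes moved to -0.112.

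All 56 interferon-stimulated genes rose in KO too (56 and 0 adjusted over the list alone, camera adjusted p = 3.75e-29, adjusted p = 0.263 with an estimated correlation). So did 44 of 46 NF-kB genes (44 and 0 adjusted over the list alone, camera adjusted p = 1.04e-24, adjusted p = 0.103 with an estimated correlation) and all 19 MHC class I genes (19 and 0 adjusted over the list alone, camera adjusted p = 5.53e-13, adjusted p = 0.168 with an estimated correlation). Of the focus genes 16 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 2.22e-08, adjusted p = 0.131 with an estimated correlation), the latter being Igf2bp2 at -0.97 ± 0.15. Casp8 rose by 0.39 ± 0.10 (adjusted p = 0.0199) and Mettl3 by 0.50 ± 0.14 (adjusted p = 0.0261). The Casp8 call was lost without either KO PBS library or either stimulated KO library (adjusted p up to 0.108) and the Mettl3 call without either KO PBS library or stimulated KO library 1 (up to 0.14). Of the NRF2 and oxidative stress list 4 genes rose and 10 fell (6 and 10 adjusted over the list alone, camera adjusted p = 0.484), with catalase, Cat, at -1.65 ± 0.07. Of the mitochondrially encoded mRNAs 0 rose and 9 fell (0 and 9 adjusted over the list alone, camera adjusted p = 3.04e-04, adjusted p = 0.428 with an estimated correlation), with mt-Cytb at -1.33 ± 0.07. Of 29 lysosomal genes 4 rose and 18 fell (5 and 19 adjusted over the list alone, camera adjusted p = 0.00237, adjusted p = 0.58 with an estimated correlation), including the lysosomal lipase Lipa (-2.56 ± 0.08). Of 22 cholesterol synthesis genes 8 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0331, adjusted p = 0.302 with an estimated correlation), with 0 to 1 fallen without 1 library. Stromal markers split into 4 up and 4 down (4 and 4 adjusted over the list alone, camera adjusted p = 0.806), with 2 to 4 up without 1 library. Ribosomal proteins rose more often than they fell in WT, which turned to 3 up and 10 down with library size alone. None of them passed in the difference of both responses. In KO this list had 1 up and 7 down of 45 (0 and 2 adjusted over the list alone, camera adjusted p = 0.199). This became 0 and 19 with library size alone, and 0 to 1 up and 2 to 11 down without 1 library.

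Across the 17470 genes the responses of both genotypes correlated with Pearson's r = 0.723 and Spearman's rho = 0.763, a description across genes, which are not independent replicates. The r was 0.599 to 0.626 when any 1 library was left out, 0.426 with no filter on low counts and 0.919 with a stricter one. Of the genes that rose in WT 2899 also rose in KO, against 725 for independent lists, and 2630 fell in both, against 662. Of the genes that rose in WT 13 fell in KO, and 11 fell in WT and rose in KO. These responses share no library.

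The third comparison asked what differed between KO and WT before stimulation. KO cells also carry Cre and WT cells do not, so effects of Mettl3 deletion and of Cre cannot be told apart. KO macrophages with PBS carried more mRNA of some antigen presentation genes. The MHC class II chain H2-Aa was higher by 1.35 ± 0.12 (804 ± 85.5 against 315 ± 28.4 CPM, SD, n = 2), and the class I genes H2-Q6 and H2-Q7 by 1.47 ± 0.07 and 1.51 ± 0.07. The acute-phase gene Saa3 was higher by 0.97 ± 0.07, the complement protease C1ra by 1.74 ± 0.12, the tetraspanin Tspan7 by 2.06 ± 0.14 and Ctsk, the collagen-degrading cathepsin K, by 1.53 ± 0.09. The immunoglobulin heavy chain gene Ighg2b, a plasma cell product, had 0 counts in WT with PBS and was at least 765-fold higher in KO. Lyz2, lysozyme, the gene whose promoter drives Cre in these mice, was lower by -0.99 ± 0.06 (17100 ± 522 against 34100 ± 1880 CPM). Since only KO mice carry that Cre, the Lyz2 difference cannot be assigned to Mettl3 deletion. The endonuclease subunit Eme2 was lower by -3.03 ± 0.22 and Golph3l, a Golgi protein, by -1.31 ± 0.08, while the zinc finger gene Zfp180 was higher by 2.72 ± 0.17. The largest adjusted p among these genes was 0.00507, for Ighg2b. They are among the 13 of 50 genes, taken by the naming rule and called here, that passed in all 8 fits that left out 1 library. Of the focus list Mettl3 alone passed, with 3 higher and 5 lower adjusted over the list alone. Zbp1 differed by 0.53 ± 0.16 (adjusted p = 0.195), Nlrp3 by 0.07 ± 0.12 (adjusted p = 0.871), Casp1 by -0.37 ± 0.10 (adjusted p = 0.145) and Il1b by -0.05 ± 0.12 (adjusted p = 0.907).

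Of 14 MHC class II genes 6 were higher in KO and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 1.69e-07, adjusted p = 0.342 with an estimated correlation). The count was 1 to 6 when 1 library was left out. Of 15 stromal markers, which BMDM should carry at low levels, 6 were higher and 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 6.26e-13, adjusted p = 0.342 with an estimated correlation), and 0 to 4 were higher without 1 library. Their summed level was 635 ± 24.3 CPM in KO and 402 ± 31.1 in WT. The matrix genes Dcn (0.84 ± 0.10) and Col3a1 (0.66 ± 0.09) lost their calls, Dcn without either WT PBS library or either KO PBS library (adjusted p up to 0.0876) and Col3a1 without either WT PBS library, either KO PBS library or either stimulated KO library (up to 0.109). Of 7 B and plasma cell genes the light chain Igkc (2.80 ± 0.31) and the joining chain Jchain (2.80 ± 0.35) were higher (2 and 1 adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.581 with an estimated correlation). The summed level of that list was 56.9 ± 5.53 CPM in KO and 56.8 ± 0.0531 in WT, and 0 to 2 of its genes were higher without 1 library. Igkc lost the call without either KO PBS library (adjusted p up to 0.0621) and Jchain without WT PBS library 1, either KO PBS library or stimulated KO library 2 (up to 0.0847).

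Of 19 MHC class I genes 3 were higher in KO with PBS (8 and 0 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.642 with an estimated correlation), and 5 and 0 were higher and lower without a composition factor. Of 56 interferon-stimulated genes 5 were higher (7 and 0 adjusted over the list alone, camera adjusted p = 0.00292, adjusted p = 0.737 with an estimated correlation), such as Irf7 (0.76 ± 0.10) and Ifi44 (0.99 ± 0.11). Irf7 lost the call without WT PBS library 1 or either KO PBS library (adjusted p up to 0.103) and Ifi44 without either WT PBS library or either KO PBS library (up to 0.0848). Of 46 NF-kB genes 4 were higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.0323, adjusted p = 0.642 with an estimated correlation), and of 34 genes of the stress responses 5 (8 and 2 adjusted over the list alone, camera adjusted p = 0.11). The latter included Calr, a chaperone of the endoplasmic reticulum (0.58 ± 0.06), whose call was lost without either WT PBS library or KO PBS library 2 (adjusted p up to 0.0684). Without 1 library the counts higher were 0 to 4 for the interferon, 1 to 3 for the NF-kB and 0 to 6 for the stress response list. Macrophage core genes had 2 higher and 3 lower, which became 5 and 3 without a composition factor (8 and 6 adjusted over the list alone, camera adjusted p = 0.871). Without 1 library 0 to 4 core genes were higher and 1 to 3 lower. Ribosomal protein genes shifted up in camera with 0 members past the threshold (0 and 0 adjusted over the list alone, camera adjusted p = 6.16e-04, adjusted p = 0.737 with an estimated correlation), as did G2 and M phase genes with 0 (0 and 0 adjusted over the list alone, camera adjusted p = 0.00292, adjusted p = 0.66 with an estimated correlation). Autophagy genes shifted down with 0 members past it (0 and 0 adjusted over the list alone, camera adjusted p = 0.00159, adjusted p = 0.342 with an estimated correlation), as did erythroid genes with 0 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0323, adjusted p = 0.642 with an estimated correlation). None of the 22 NRF2 genes passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.943).

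In total 271 genes differed by genotype with PBS, 209 higher and 62 lower in KO (2690 at an unadjusted p under 0.05). DESeq2 called 850, of which 65.4% were higher, against 77.1% in edgeR. The count was 91 and 121 without WT PBS library 1 and 2, 112 and 80 without KO PBS library 1 and 2, and 132 and 131 without stimulated KO library 1 and 2. With only the 4 PBS libraries fitted it was 45.

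The fourth comparison asked what differed between KO and WT after stimulation, where deletion and Cre again cannot be told apart. Stimulated KO macrophages carried less mRNA of some antioxidant enzymes. Prdx1 was lower by -1.46 ± 0.07 (1420 ± 12.4 against 3910 ± 317 CPM), Cat by -1.14 ± 0.07, Hmox1 by -1.07 ± 0.07 and the autophagy receptor Sqstm1 by -1.11 ± 0.08. The lipid desaturase Scd2 was lower by -1.61 ± 0.08, the fatty acid transporter Cd36 by -1.25 ± 0.07, the stress transcription factor Atf5 by -1.37 ± 0.09, the kinase Sgk1 by -1.04 ± 0.06 and the cochaperone Dnajb4 by -1.65 ± 0.08. Lyz2 was lower by -1.14 ± 0.06, which again cannot be assigned to Mettl3 deletion. Some matrix and stromal genes were higher, Col3a1 by 1.59 ± 0.09, Dcn by 1.52 ± 0.10 and Cxcl12 by 2.18 ± 0.15. So were the calcitonin receptor Calcr (3.13 ± 0.22), the haemoglobin scavenger receptor Cd163 (1.54 ± 0.15), the purine receptor P2ry13 (2.19 ± 0.17) and Lrmda (3.63 ± 0.23). Ifi208, of the PYHIN family whose members resemble one another, stood at 64.3 ± 1.45 CPM in KO and 0.89 ± 0.153 in WT. The largest adjusted p among these genes was 0.00634, for Ifi208. They are among the 30 of 79 genes, taken by the naming rule and called here, that passed in all 8 fits that left out 1 library.

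The inflammasome genes of the focus list did not differ by genotype past the threshold. Zbp1 differed by 0.16 ± 0.16 (483 ± 2.87 against 432 ± 14.1 CPM, adjusted p = 0.642), Nlrp3 by -0.00 ± 0.12 (adjusted p = 1), Gsdmd by -0.08 ± 0.07 (adjusted p = 0.571) and Casp4 by 0.02 ± 0.08 (adjusted p = 0.956). Il1b, at 1500 ± 139 against 1050 ± 32.5 CPM, differed by 0.51 ± 0.12 (adjusted p = 0.0591) and Casp1 by -0.45 ± 0.10 (adjusted p = 0.0508), both just short of the threshold. Of the focus list 1 gene was higher and 2 lower, which became 4 and 2 without a composition factor (5 and 5 adjusted over the list alone, camera adjusted p = 0.872). In the wider inflammasome list 1 was higher and 1 lower (4 and 3 adjusted over the list alone, camera adjusted p = 0.822), and in the interferon list 1 was higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.289). The inflammasome counts became 4 and 1 without a composition factor. Without 1 library the counts higher and lower were 0 to 1 and 1 to 2 for the focus list and 0 to 1 and 0 to 1 for the inflammasome list. Of 46 NF-kB genes 4 were higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.425 with an estimated correlation). These became 10 and 1 without a composition factor, and 0 to 3 were higher without 1 library. Among them the neutrophil chemokine Cxcl5 was higher by 3.18 ± 0.40 and Nos2 lower by -1.08 ± 0.09. Cxcl5 lost the call without either stimulated WT library or stimulated KO library 1 (adjusted p up to 0.0698) and Nos2 without either stimulated KO library (up to 0.0694).

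By group, 10 of 22 NRF2 and oxidative stress genes were lower and 0 higher in stimulated KO, counts that were 2 higher and 16 lower adjusted over the list alone (camera adjusted p = 1.91e-08, adjusted p = 0.18 with an estimated correlation). When 1 library was left out, 7 to 10 were lower. Of the mitochondrially encoded mRNAs 6 of 13 were lower, or 10 adjusted over the list alone (camera adjusted p = 3.76e-09, adjusted p = 0.274 with an estimated correlation), and 5 to 9 without 1 library. Of these mt-Cytb was lower by -0.95 ± 0.07 and mt-Nd5 by -0.83 ± 0.06, both kept in all 8 fits. Several mitochondrial genes have near-identical nuclear copies on chromosome 1 that may take part of their counts. Stromal markers were higher in 13 of 15 cases (14 and 0 adjusted over the list alone, camera adjusted p = 6.49e-18, adjusted p = 0.174 with an estimated correlation), with a summed level of 630 ± 60.8 CPM in KO and 244 ± 0.373 in WT, and in 10 to 13 cases without 1 library. Of 7 B and plasma cell genes 4 were higher (5 and 0 adjusted over the list alone, camera adjusted p = 6.97e-06, adjusted p = 0.174 with an estimated correlation), with sums of 45.1 ± 6.1 and 13.2 ± 2.46 CPM, and 0 to 3 without 1 library.

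Of 32 G2 and M phase genes 10 were higher in stimulated KO (20 and 0 adjusted over the list alone, camera adjusted p = 2.20e-11, adjusted p = 0.223 with an estimated correlation), or 0 to 9 without 1 library, among them the cyclin Ccna2 (1.92 ± 0.30). Ccna2 lost the call without stimulated WT library 1 or either stimulated KO library (adjusted p up to 0.106). Of 28 hypoxia and glycolysis genes 5 were higher (12 and 2 adjusted over the list alone, camera adjusted p = 0.00378, adjusted p = 0.204 with an estimated correlation), or 0 to 4 without 1 library. Of 22 cholesterol genes 2 were higher (8 and 0 adjusted over the list alone, camera adjusted p = 1.13e-06, adjusted p = 0.174 with an estimated correlation), and of 14 MHC class II genes 4 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 2.63e-04, adjusted p = 0.243 with an estimated correlation). LXR and lipid genes had 1 higher and 4 lower (1 and 8 adjusted over the list alone, camera adjusted p = 0.00175, adjusted p = 0.174 with an estimated correlation). The stress response list had 7 higher and 8 lower (10 and 12 adjusted over the list alone, camera adjusted p = 0.113), which became 8 and 7 without a composition factor. Lysosomal genes had 2 higher and 4 lower (4 and 11 adjusted over the list alone, camera adjusted p = 0.0326, adjusted p = 0.763 with an estimated correlation), which became 5 and 4 without that factor. Macrophage core genes had 1 higher and 7 lower (7 and 11 adjusted over the list alone, camera adjusted p = 0.206), which became 8 and 6 without it. Without 1 library the MHC class II genes higher were 0 to 4, the LXR genes lower 2 to 3, the macrophage core genes lower 2 to 7, the macrophage core genes higher 0 to 4, the stress response genes higher 0 to 6 and lower 2 to 9, the lysosomal genes higher 1 to 2 and lower 0 to 6, and the cholesterol genes higher 0 to 1. With library size alone the counts were 8 and 0 for cholesterol, 10 and 0 for hypoxia, 16 and 0 for G2 and M phase and 7 and 1 for MHC class II.

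**Figure D2:**
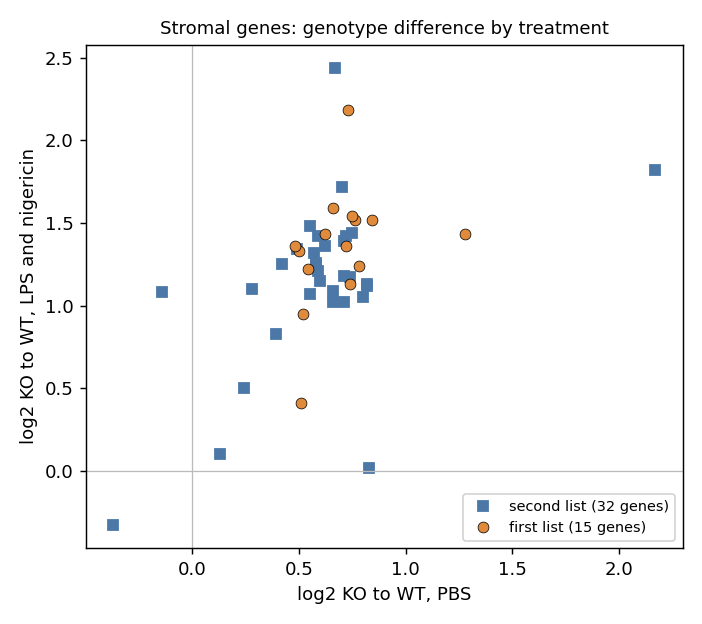
Each point is a stromal gene, placed by its log2 difference between KO and WT with PBS (horizontal axis) and after LPS and nigericin (vertical axis), with circles for the 15 genes of the first list and squares for 32 genes of a second list. Of the second list 30 genes lay above 0 with PBS and 31 after stimulation.

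In total 860 genes differed by genotype after stimulation, 508 higher and 352 lower in KO (3470 at an unadjusted p under 0.05). Without a composition factor the median of all genes moved to 0.127 and 81.6% of changed genes were higher, against 59.1%. DESeq2 called 1638 genes and a fit of the 4 stimulated libraries alone 503. The count was 156 and 249 without stimulated KO library 1 and 2, and 487 and 460 without stimulated WT library 1 and 2. Of the genes higher in KO with PBS 96 were also higher after stimulation, against 6.1 for independent lists (Fisher's exact test, two-sided, p = 4.33e-92), and 33 were lower in both, against 1.2 (Fisher's exact test, p = 5.86e-40). In opposite directions 6 and 2 genes passed (Fisher's exact test, p = 0.321 and p = 0.702). These p-values are a description, since genes are not independent and both lists come from the same fit. The shared total of 129 was 31 and 34 without stimulated KO library 1 and 2, 50 and 32 without KO PBS library 1 and 2, 40 and 47 without WT PBS library 1 and 2, and 84 without stimulated WT library 1.

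The last comparison asked which genes responded to stimulation differently by genotype. Some NRF2 and oxidative stress genes had a lower response in KO. The interaction for Prdx1 was -1.57 ± 0.10 log2 units, with Prdx1 going from 1220 ± 27 to 3910 ± 317 CPM in WT and from 1310 ± 29.3 to 1420 ± 12.4 in KO. Scd2 (-1.80 ± 0.12), the scavenger receptor Marco (-2.09 ± 0.09), the arginine synthesis enzyme Ass1 (-2.14 ± 0.12) and the class I genes H2-Q6 (-1.55 ± 0.09) and H2-Q7 (-1.34 ± 0.10) also had lower responses in KO. Marco (1.71 ± 0.07) and Ass1 (1.16 ± 0.09) were already higher in KO with PBS, as were H2-Q6 and H2-Q7. Their lower responses thus started from a higher level in KO. The mitochondrial rRNA mt-Rnr1 had a higher response in KO (2.03 ± 0.12), at 190 ± 12 CPM in stimulated WT and 850 ± 24.6 in stimulated KO. Zfp180 rose in WT, from 4.18 ± 1 to 24.4 ± 0.644 CPM, and fell in KO, from 27.7 ± 0.232 to 5.24 ± 0.343 (-4.95 ± 0.24). The largest adjusted p among these interactions was 0.00535, for H2-Q7. These 8 genes, of 32 that the naming rule took and the test called, passed in every fit that left out 1 library. Zbp1 (-0.37 ± 0.23, adjusted p = 0.63), Nlrp3 (-0.07 ± 0.17, adjusted p = 0.952) and Il1b (0.55 ± 0.17, adjusted p = 0.269) did not pass.

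Of the NRF2 list 6 of 22 genes had a lower response in KO, or 13 adjusted over the list alone (camera adjusted p = 1.03e-08, adjusted p = 0.244 with an estimated correlation). The count was 1 to 6 without 1 library. Besides Prdx1 the list included Cat (-1.10 ± 0.10), which fell in both genotypes (-0.56 ± 0.07 in WT and -1.65 ± 0.07 in KO) and whose call was lost without WT PBS library 1 or either stimulated KO library (adjusted p up to 0.0754). It also included Gclm, a subunit of the glutathione synthesis enzyme (-1.85 ± 0.20), whose call was lost without WT PBS library 1, stimulated WT library 2, either KO PBS library or stimulated KO library 1 (adjusted p up to 0.0784). Gclm was at -0.13 ± 0.14 in WT (adjusted p = 0.531) and fell in KO (-1.98 ± 0.15). Of the mitochondrially encoded mRNAs 4 of 13 had a lower response, or 10 adjusted over the list alone (camera adjusted p = 1.35e-09, adjusted p = 0.43 with an estimated correlation), and 0 to 4 without 1 library. Of the stromal markers 2 of 15 had a higher one (10 and 0 adjusted over the list alone, camera adjusted p = 9.55e-10, adjusted p = 0.309 with an estimated correlation), and 0 in every fit without 1 library. None of 22 cholesterol synthesis genes passed over all genes (10 and 0 adjusted over the list alone, camera adjusted p = 2.20e-08, adjusted p = 0.244 with an estimated correlation). A lower response was also counted for 2 of 19 MHC class I genes (0 and 7 adjusted over the list alone, camera adjusted p = 8.75e-05, adjusted p = 0.482 with an estimated correlation) and 1 of 56 interferon-stimulated genes (0 and 4 adjusted over the list alone, camera adjusted p = 3.03e-04, adjusted p = 0.724 with an estimated correlation). The latter was Oasl1 at -0.76 ± 0.11, whose call was lost without any 1 of the 8 libraries (adjusted p up to 0.208). For the inflammasome list 0 genes had a higher and 1 a lower response (3 and 4 adjusted over the list alone, camera adjusted p = 0.161). With library size alone no member of the inflammasome or interferon list passed, and without any 1 library none of the inflammasome list did.

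**Figure D3:**
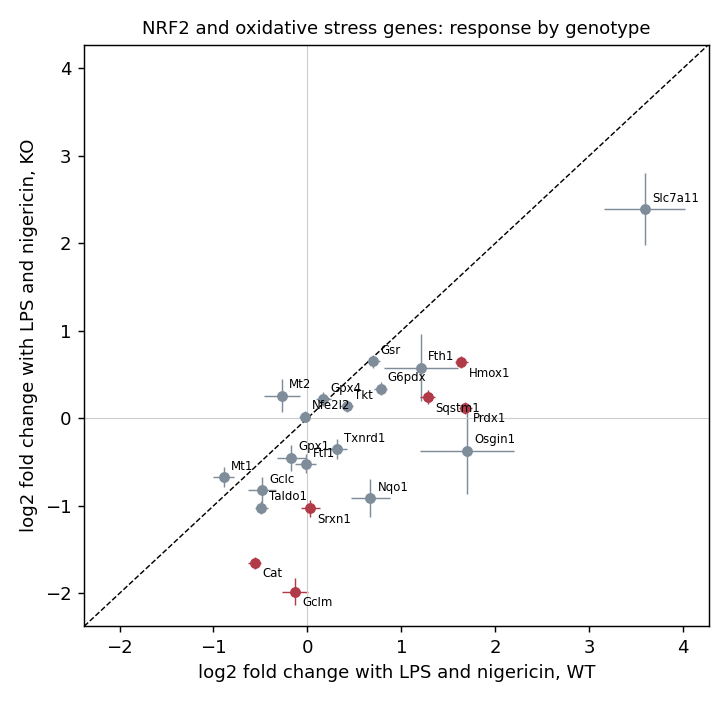
Each point is 1 of 22 NRF2 and oxidative stress genes, placed by its log2 fold change with LPS and nigericin in WT (horizontal axis) and in KO (vertical axis), with standard errors as bars and a dashed line at equal responses. Red points are the 6 genes with an interaction past adjusted p 0.05.

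**Figure D4:**
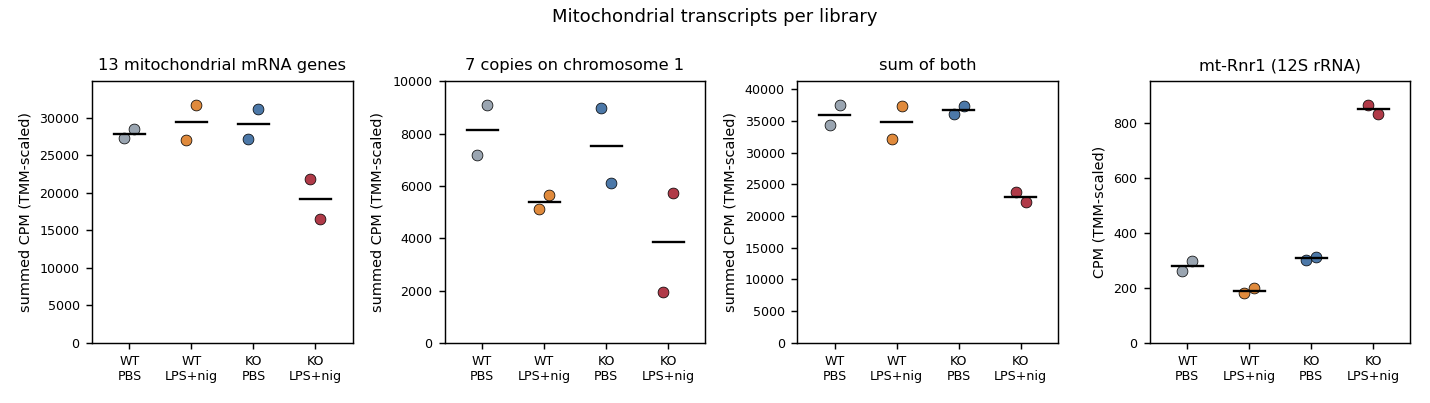
Panels show summed CPM of 13 mitochondrial mRNA genes, of 7 nuclear copies on chromosome 1, of both together, and the level of mt-Rnr1, on axes that start at 0. Points are the 2 libraries of a group and lines their mean, which for both together was 34734 in stimulated WT and 22961 in stimulated KO.

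In total 87 genes differed in response, 18 with a higher and 69 with a lower log2 response in KO (1872 at an unadjusted p under 0.05). Without a composition factor the median of all genes moved to 0.103. DESeq2 called 481 genes, of which 39.3% were higher, against 20.7% in edgeR. The count was 20 and 25 without stimulated KO library 1 and 2, 32 without WT PBS library 1, 36 without KO PBS library 2 and 49 without stimulated WT library 2.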

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

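The tests of the response slope, of the macrophage core median, of genes without poly(A) tails and of mt-Rnr1 were chosen only after the result was seen. A test of the difference between both responses singled out 87 genes, of which 32 fall under the naming rule. A higher response in KO was found for Gpr176 (3.20 ± 0.39), Eme2 (2.87 ± 0.29), mt-Rnr1 (2.03 ± 0.12), Setd6 (1.58 ± 0.16), Cxcl12 (1.45 ± 0.20), Syne2 (1.34 ± 0.19), mt-Rnr2 (1.32 ± 0.13), P4ha2 (1.27 ± 0.18), Cd14 (1.13 ± 0.13) and Col3a1 (0.93 ± 0.12). A lower response was found for Zfp180 (-4.95 ± 0.24), Fpr1 (-2.18 ± 0.23), Ass1 (-2.14 ± 0.12), Marco (-2.09 ± 0.09), Fpr2 (-1.88 ± 0.26), Gclm (-1.85 ± 0.20), Scd2 (-1.80 ± 0.12), Ptgr1 (-1.59 ± 0.13), Prdx1 (-1.57 ± 0.10), H2-Q6 (-1.55 ± 0.09) and H2-Q7 (-1.34 ± 0.10). It was also found for Atf5 (-1.10 ± 0.13), Cat (-1.10 ± 0.10), Hmox1 (-1.0 ± 0.09), Lipa (-0.94 ± 0.11), mt-Cytb (-0.95 ± 0.10), mt-Nd6 (-0.88 ± 0.09), mt-Nd2 (-0.86 ± 0.11), mt-Nd5 (-0.79 ± 0.09), Oasl1 (-0.76 ± 0.11), Psap (-0.74 ± 0.09) and Gpnmb (-0.74 ± 0.09). Zfp180, Fpr1, Fpr2, Ass1, Marco, H2-Q6 and H2-Q7 started from a higher level in KO with PBS. The calls of Zfp180, Marco, Ass1, Scd2, Prdx1, H2-Q6, H2-Q7 and mt-Rnr1 were kept in all 8 fits that left out 1 library. Each of the other 24 was lost without stimulated KO library 1, and all of these but Gclm and Ptgr1 also without stimulated KO library 2. Their highest adjusted p over the fits lay between 0.065, for Ptgr1, and 0.208, for Oasl1. Without stimulated KO library 1 the count was 20.

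Of the NRF2 and oxidative stress genes with a lower response in KO, some rose less than in WT and others fell only in KO or fell further there, and a weaker response of every gene could be the cause. The slope of the KO on the WT response was 0.944 (95% interval over resampled genes 0.926 to 0.964, 4688 genes), which argues against it in these libraries. Dilution of macrophage RNA by other cells would lower macrophage core genes as much, and it stays open. Their median of -0.027 (95% interval over resampled genes -0.335 to 0.156) lay above the -0.706 of the NRF2 list. That gap was less than the SD of 0.769 over the 27 members, which went both ways. The summed core level was 50100 ± 742 CPM in KO and 74800 ± 3340 in WT. This sum cannot decide it, since Lyz2, the Cre driver, was at 15100 ± 467 and 33300 ± 1560 of it. With PBS, where none of the NRF2 genes passed, the sum was also lower in KO (68700 ± 2580 against 85000 ± 3430). In stimulated KO 1 core gene was higher and 7 lower, but of the interferon-stimulated genes 1 was higher and 0 lower. A lowering of all such lists alike was thus not seen. With DESeq2's factors 6 members and with no composition factor 5 members had a lower response, and without the factor Prdx1 was at -1.46, Gclm at -1.75 and Cat at -0.99, which argues against scaling as the whole cause for these genes. These tests leave dilution and a change in the regulation or decay of these mRNAs open, and none of them tells these from differences between cultures.

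In stimulated KO 6 of 13 mitochondrial mRNAs were lower (camera adjusted p = 3.76e-09, adjusted p = 0.274 with an estimated correlation, and 5 to 9 genes without 1 library) and mt-Rnr1 and mt-Rnr2 were higher. Weaker removal of RNA without poly(A) tails would raise histone and other such RNAs. Their median was -0.689 (95% interval over resampled genes -0.978 to -0.422, 21 genes). This cannot decide whether weaker removal explains the rRNAs. Histones are 16 of these genes, and their sum was already lower in KO with PBS (153 ± 9.86 against 218 ± 27.7 CPM). Of the 5 other RNAs 0 passed the threshold. That mt-Rnr1 was higher by 2.16 is part of the pattern itself, so it leaves open whether there was less mitochondrial RNA apart from the rRNAs. Reads shared with nuclear copies would leave the sum of the 13 genes and the 7 copies unchanged, but it differed by -0.6, with 23702 and 22219 CPM in KO and 32139 and 37330 in WT. The 4 genes outside the copied segment differed by -0.79.

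Some stromal markers were higher in KO, 6 of 15 with PBS (adjusted p = 0.342 with an estimated correlation, 0 to 4 genes without 1 library) and 13 after stimulation (adjusted p = 0.174 with an estimated correlation). Stromal genes outside the first list had a median of 1.174 after stimulation (95% interval over resampled genes 1.097 to 1.303). Of these, 31 of 32 were higher, 23 called higher and 1 lower, which is what more stromal RNA in the stimulated KO cultures needs. With PBS their median was 0.61 (30 of 32 higher, 2 called higher and 1 lower). B and plasma genes outside the first list had a median of 1.332 after stimulation (95% interval over resampled genes 0.986 to 3.394). Of these, 11 of 13 were higher, 1 called higher and 1 lower. With PBS their median was 1.738 (9 of 11 higher, 3 called higher and 1 lower), and both medians came from few counts. These intervals do not measure the spread between libraries. The summed first B and plasma list was 56.9 ± 5.53 CPM in KO and 56.8 ± 0.0531 in WT with PBS, and 45.1 ± 6.1 and 13.2 ± 2.46 after stimulation. With 2 libraries per group a difference between the cultures cannot be separated from an effect of genotype, and expression of these genes by macrophages could not be excluded and was not tested.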

How the results depend on the processing

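No alternative below was chosen after the result was seen. The 5 counts of changed genes stayed within 1.5 times under DESeq2's size factors, limma-voom and both filters. No named gene that passed in the main fit or in the alternative reversed its direction. Changes of sign in genes that passed in neither were not counted. Among named genes 8774 comparisons with an alternative kept their side of the threshold, 624 lost it and 100 gained it. DESeq2 called 850 genes by genotype with PBS, 1638 after stimulation, 481 in the difference of responses and 365 shared by both treatments. Without a composition factor 201 were shared. The correlation of responses was 0.426 with no filter and 0.919 with the stricter one, which test 25411 and 10591 genes. With only the groups compared in the fit, 45 genes passed with PBS, 503 after stimulation and 17 in both, with r = 0.827, from fewer libraries, and the difference of responses could not be fitted. Requiring 2-fold left 3429, 3261, 120, 368 and 51 genes in the 5 contrasts and 41 shared, since it takes fewer genes by construction. Leaving out 1 library gave 5268 to 6711 genes for WT, 4961 to 7011 for KO, 80 to 260 with PBS, 156 to 594 after stimulation, 20 to 99 in the difference, 31 to 97 shared and r of 0.599 to 0.626. The lone library left in a group was assumed to vary like the other groups. For DESeq2 and the composition factor the cause was not tested. With the replicate number as a replicate block, 6866, 6656, 229, 672 and 60 genes passed and 107 were shared. Correlations of same-numbered deviations were -0.047 to 0.338 over 8643 genes, the highest between WT and KO with PBS. On the fifth principal component (5.4% of the variance) libraries 1 and 2 stood at -29.47 and 32.48 in WT with PBS. In KO with PBS they stood at -43.02 and 41.26, and the stimulated libraries lay between -5.91 and 5.2. The PBS groups thus shared a difference by library number, but whether it marks a shared batch stays open. Alternatives for tables of normalized values (pseudocount, quantile scaling) were not run, since the table holds counts. Depth limits genes with few counts, such as immunoglobulin genes.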

Other observations

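The test of an LPS-like state, the test by chromosome and the test of the Lyz2 flank alone were chosen only after the result was seen, as were the genes of the next paragraph.

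Several genes outside the naming rule were higher in KO before stimulation. C3, the central complement component, was higher by 1.67 ± 0.07 (adjusted p = 4.72e-04) with PBS and by 0.80 ± 0.06 (adjusted p = 0.00224) after stimulation. Cfb, complement factor B, was higher by 0.95 ± 0.05 (adjusted p = 0.00126) with PBS and at 0.11 ± 0.05 (adjusted p = 0.311) after stimulation. The NAD-degrading enzyme Cd38 was higher by 1.27 ± 0.09 with PBS and at 0.15 ± 0.08 (adjusted p = 0.333) after stimulation. Von Willebrand factor, Vwf, was higher by 1.59 ± 0.08 with PBS and by 0.37 ± 0.08 (adjusted p = 0.046) after stimulation. Fpr1, the receptor for bacterial formyl peptides, was higher by 2.20 ± 0.18 (adjusted p = 0.0034) with PBS and at 0.02 ± 0.14 (adjusted p = 0.974) after stimulation. Marco was higher by 1.71 ± 0.07 (adjusted p = 4.72e-04) with PBS and lower by -0.38 ± 0.06 (adjusted p = 0.0196) after it. Clec5a, a myeloid lectin receptor, was higher by 1.09 ± 0.08 with PBS and 1.37 ± 0.08 after stimulation. Genotype differences of opposite sign passed in both treatments for 8 genes. The largest were those of the processed pseudogene Gm12435 (-3.89 and 4.0), at 49.5 and 33.7 CPM in the libraries of WT with PBS, 2.64 and 3.05 in stimulated WT, 3.15 and 2.45 in KO with PBS and 30.6 and 60.4 in stimulated KO. Zfp180 (2.72 and -2.22) had the mirror image of these levels, so neither gene had a level that goes with genotype or treatment alone. Others of the 8 were Ass1 (1.16 and -0.98) and Setd6 (-0.72 and 0.86).

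One hypothesis was that KO macrophages were in a weak LPS-like state before stimulation. Of the 209 genes higher in KO with PBS, 115 rose with LPS and nigericin in KO, 2.73 times the 42.2 of independent lists (Fisher's exact test, two-sided, p = 5.86e-29), and 41 fell. The KO PBS libraries enter both comparisons, which by itself pushes them apart. Simulated groups without any response had a correlation of -0.502 and a covariance of -0.1377, against -0.097 and -0.0897 observed. Only the observed data hold a real response to stimulation, so the gap between the correlations does not measure such a state. Fisher's test also treats genes as independent, which they are not. The overlap is in line with such a state, and it could equally come from cultures that differed before treatment.

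Another hypothesis was that genes near Mettl3 or Lyz2 differ because they come from the strain in which the alleles were made. Of 127 genes that differed by genotype in both treatments in 1 direction, Mettl3 and Lyz2 themselves left out, 3 lay within 10 Mb of either gene, an odds ratio of 1.29 (95% interval 0.26 to 3.89, Fisher's exact test, two-sided, p = 0.51). That bound was set for both genes, but both Mettl3 alleles are floxed in WT and KO alike, so only the Lyz2 flank should differ by genotype. All 3 lay near Mettl3 and 0 near Lyz2, where 98 genes were tested and 0.713 were expected (odds ratio 0, 95% interval 0 to 5.28, Fisher's exact test, two-sided, p = 1), too few genes to decide, so linkage to Lyz2 stays open. Chromosome 6 held 17 of these genes against 6.6 expected (Fisher's exact test, two-sided, adjusted p = 0.0059 over 20 chromosomes, Y left out). Of the 17, 4 are kappa light chain genes, and Vwf, Eno2, Slc6a12, Gdf3, C1rl and C1ra lie within 1 stretch of 10 Mb. Eif2s3y, on the Y chromosome, was also among the 127 genes, where 5 genes were tested and 0.04 were expected. A difference in sex between the mice was not tested.

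Some abundant genes differed widely between the libraries of 1 group. Arhgap19 was at 26.8 and 259.9 CPM in KO with PBS, Tlr7 at 63.5 and 284.1 in WT with PBS and Sirpa at 1619.9 and 646.3 in stimulated KO. Gm4070 was at 338.1 and 0.7 in stimulated WT. Of the nuclear copies of mitochondrial genes, Gm10925 was at 66.5 and 1012 and Gm28437 at 167.9 and 1021.1 in stimulated KO. For some the direction repeated by library number. mt-Atp6 was at 490.6 and 1847.6 in WT with PBS, 577.1 and 2955.3 in stimulated WT and 430.8 and 2414.9 in KO with PBS, but at 547 and 249 in stimulated KO. Nfe2l1 was at 191.7 and 59.4 in WT with PBS and 465 and 109.6 in stimulated WT, and Cyth1 at 216.5 and 70.6 in WT with PBS and 180.9 and 49.8 in KO with PBS. Ifi47 went in opposite directions, at 87.8 and 237.3 in stimulated WT and 296.4 and 112.5 in stimulated KO. These genes were chosen after their values were seen.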
